A study of Mus musculus with 15 samples.

How the data were processed

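The series measured gene expression on 1-colour Affymetrix arrays in adipocytes sorted by flow cytometry from mice aged 8 to 10 weeks. Total RNA (2 ng) was amplified and biotin-labelled with the WT Pico kit, per the labels. Of the 15 arrays analysed, 4 held UCP1-negative white adipocytes from inguinal fat of untreated mice (WAT). Another 3 held UCP1-positive brown adipocytes from brown fat of untreated mice (BAT). The others held UCP1-positive adipocytes from inguinal fat of treated mice, with 3 arrays after CL316243 (CL), 2 after roscovitine (RS) and 3 after rosiglitazone (RG). The labels call the gate UCP1(GFP) but the mice UCP1/Tomato, so the reporter behind the gate is not settled. The third RS array of the series was not analysed here. The labels give no dose, no treatment time, no sex, no array batch and no statement of whether arrays came from separate animals.

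The deposited values are log2 expression values, 1 per probe set and array. The submitters' processing notes name RMA, affy 1.36.1 and Affymetrix Expression Console, without their order, their settings or the probe-set definition. The deposited table held 25206 probe sets per array with no missing value. Of these, 23185 were given 1 gene symbol through the Entrez number in their identifier, 2021 had no symbol, and none had several. All probe sets were tested and no values were filtered out. Arrays carry no read depth, so the number of arrays limits the precision. Array medians lay between 3.33 and 3.47, and the standard deviation over probe sets lay between 1.65 and 2.00. The standard deviation was 1.91 to 2.00 in the WAT arrays and 1.65 to 1.85 in all others, so the range of values differs between these groups.

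Differences between groups were tested with limma 3.58.1 in R 4.3.3. The functions lmFit, contrasts.fit and eBayes fitted all 15 arrays in 1 model with a mean per group, which left 10 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all probe sets within each comparison and a threshold of 0.05. The comparisons were BAT, CL, RS and RG against WAT, RS against CL and RS against RG, and, as secondary ones, CL against RG and RS, CL and RG against BAT. P-values measure the spread between these samples. RS holds 2 arrays, and its spread was taken to be like that of the other groups. In simulated data with known changes, the same test recovered 93.9% of genes raised or lowered by 2 log2 units in BAT against WAT and 93.9% in RS against CL. At a change of 1 log2 unit it recovered 55.2% and 34.3%. The simulated genes were independent and few of them changed, so these shares may not carry over to the real data.

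Arrays of different groups share replicate numbers in their titles. After the group means were removed, 24 pairs of same-numbered arrays correlated, across probe sets, between -0.88 and -0.05, and none of the 15 arrays correlated best with an array of its own number. The numbers were therefore not used as pairs. The replicate number explained a median of 5.69% of the variation within groups, where 30% is the expectation with no effect. A model with the number as a fixed block leaves 7 residual degrees of freedom, and its counts are given beside the unblocked ones. In simulated unchanged data from which a number effect had been subtracted, 11.8% of genes had an unadjusted p under 0.05 without the block and 4.96% with it.

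In all, 37 gene lists and 15 marker genes were fixed before the data were examined. Not every list and marker gene is described for every comparison. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists within each comparison. Camera with an estimated correlation and the directional fry test were run beside it. No list kept an adjusted p under 0.05 with the estimated correlation in any comparison. Members were counted as higher or lower at an adjusted p under 0.05 over all genes and, separately, adjusted over the list alone. Where several probe sets carried 1 symbol, the one with the highest mean was used.

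Named genes followed a fixed rule. Among genes past the threshold whose arrays did not overlap between the groups, the 8 with the largest increase and the 8 with the largest decrease were taken in each main comparison, and 4 of each in each secondary one. Predicted, receptor-family, small RNA and antigen-receptor segment genes were left out. Up to 4 members with the smallest p were taken as examples from each list described.

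A position index placed each array on a line from the mean of the WAT arrays (0) to the mean of the BAT arrays (1). It is the least-squares slope through 0, over the genes called in BAT against WAT, of the array minus the WAT mean on the BAT mean minus the WAT mean. Index differences were tested with a two-sided exact permutation test. Overlaps of genes called against the shared WAT arrays were set beside the count expected for independent lists, 50 simulations, and 6 ways of dividing WAT 2 and 2. In the simulations every array, WAT included, was independent noise with the estimated spread of each gene, and the simulated WAT group was shared.

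The alternatives tried were a fit of only the 2 groups compared, the block, quantile normalization again, median centring, filters on the dimmest 25% and 50% of probe sets, an intensity trend with robust estimation, array weights, a 2-fold minimum, an adjusted p under 0.1 and each array left out in turn. Leaving out WAT 4 and RS 3 together, and the position index over only the genes higher or only the genes lower in BAT, were chosen after seeing the data.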

Results

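Gene expression was measured in sorted mouse adipocytes in 5 groups. White adipocytes (WAT, 4 arrays) lacked UCP1, the uncoupling protein of heat-producing fat cells, and came from inguinal fat of untreated mice. Brown adipocytes (BAT, 3 arrays) carried UCP1 and came from brown fat of untreated mice. UCP1-positive adipocytes from inguinal fat followed 3 treatments. These were CL316243 (CL, 3 arrays), an agonist of the beta-adrenergic receptor of adipocytes, roscovitine (RS, 2 arrays), an inhibitor of cyclin-dependent kinases, and rosiglitazone (RG, 3 arrays), an agonist of the nuclear receptor PPARG. Values are log2 expression values for 25206 probe sets, each named by the Entrez number of its gene. The files give no genome build or positions. Arrays of 1 group correlated with each other between 0.945 and 0.988 across probe sets. The first principal component held 41.4% of the variance and the second 12.1%. No untreated UCP1-positive inguinal cells were measured, so every comparison of a treated group with WAT crosses the treatment with the sorting gate. Cells were gated on UCP1, so higher Ucp1 in BAT, CL, RS and RG than in WAT was selected for by the sort. Its fold and p against WAT are therefore no independent finding. The thermogenic and PPARG target lists both hold Ucp1.

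BAT against WAT asks what sets brown adipocytes apart from white ones. Ucp1 was 115-fold higher in BAT (log2 difference 6.85 ± 0.465, SE, n = 3 and 4, adjusted p = 4.08e-07). Elovl3, a fatty acid elongase, was 60.2-fold higher, Slc27a2, a fatty acid transporter and acyl-CoA synthetase, was 32.7-fold higher, and Cox7a1, a subunit of cytochrome c oxidase, was 28.8-fold higher. Cidea, a lipid droplet protein, rose 25.2-fold, Otop1, a proton channel, 14.8-fold, Acot11, an acyl-CoA thioesterase, 14.3-fold and Kng2, a kininogen, 12.2-fold. Of the 29 measured thermogenic genes, 26 rose and none fell, with a median log2 difference of 2.57 (26 adjusted over the list alone). That list had an adjusted p = 1e-14 with the preset correlation and an adjusted p = 0.134 with an estimated correlation. Fuel-burning pathways were higher too. Fatty acid oxidation rose in 22 of 25 genes and fell in 1 (the same counts adjusted over the list alone), with an adjusted p = 1.14e-08, and an adjusted p = 0.265 with an estimated correlation. In oxidative phosphorylation, 62 of 69 genes rose (63 adjusted over the list alone), at an adjusted p = 4.44e-16, or an adjusted p = 0.286 with an estimated correlation.

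The largest decreases in BAT included genes of immune cells. Plac8 fell 22.2-fold, the lectins Cd209g and Cd209f fell 18.9-fold and 17.6-fold, and Tlr8, an RNA sensor of myeloid cells, fell to a mean below that of the 10th percentiles of the BAT arrays. H2-DMb2, which loads MHC class II molecules, fell 14.9-fold, the chemokines Ccl6 and Ccl8 14.4-fold and 14.2-fold, and Lbp, which binds lipopolysaccharide, 14.2-fold. All 22 macrophage markers fell, with a median log2 difference of -2.67 (22 adjusted over the list alone). Its adjusted p was 6.51e-17, and adjusted p = 0.134 with an estimated correlation. Stromal and preadipocyte markers fell in 16 of 20 genes (16 adjusted over the list alone), among them Sfrp4, a Wnt modulator, by 3.45 log2 units, with an adjusted p = 9.18e-10, and adjusted p = 0.176 with an estimated correlation. Endothelial markers fell in 1 of 20 genes (0 adjusted over the list alone), with an adjusted p = 0.0547, and adjusted p = 0.669 with an estimated correlation. Mature adipocyte genes rose in 9 of 27 (9 adjusted over the list alone), with an adjusted p = 0.0156, and adjusted p = 0.628 with an estimated correlation. Adipoq, which encodes adiponectin, did not differ (log2 difference 0.21 ± 0.451, adjusted p = 0.721). WAT 4 stood apart in these genes: its mean level of mature adipocyte genes was -1.55 against a range of -0.59 to -0.08 in the other WAT arrays, each relative to the mean of all arrays. Its macrophage level was 2.42, above 1.27 to 1.57 in the others.

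Markers used to name adipocyte types were counted in the same way. Of 15 classical brown markers, 5 rose and 1 fell (the same counts adjusted over the list alone), with an adjusted p = 0.457, and adjusted p = 0.541 with an estimated correlation. Zic1, a transcription factor of brown fat, rose 2.22-fold. White-selective markers fell in 10 of 20 genes and rose in 1 (12 and 1 adjusted over the list alone), with an adjusted p = 7.85e-05, and adjusted p = 0.134 with an estimated correlation. Lep, Lhx8, Tbx1, Tmem26 and Tnfrsf9 did not pass the test, with log2 differences between -0.63 and 0.21. The mean level of beige-selective markers lay between -0.200 (RS 3) and 0.247 (CL 3) on every array of the 5 groups, relative to the mean of all arrays. Only 5 of the 12 measured beige-selective markers and 3 of the 15 classical brown ones had a mean over 5 across all arrays. With few strong signals, small differences in these lists do not show that the groups are alike in these markers. In all, 11096 of 25206 probe sets changed, 6950 higher and 4146 lower in BAT. With the replicate number as a block 7286 were called, and without both WAT 4 and RS 3, an exclusion chosen after seeing the data, 9798. The median of all probe sets lay 0.18 above 0, and centring arrays on their medians brought the share called higher from 62.6% to 51.5%, so directions are relative to that shift. The 1354 olfactory and vomeronasal receptor probe sets had a median of 0.63, and 776 of them were called higher, against 166 after quantile normalization.

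**Figure D1:**
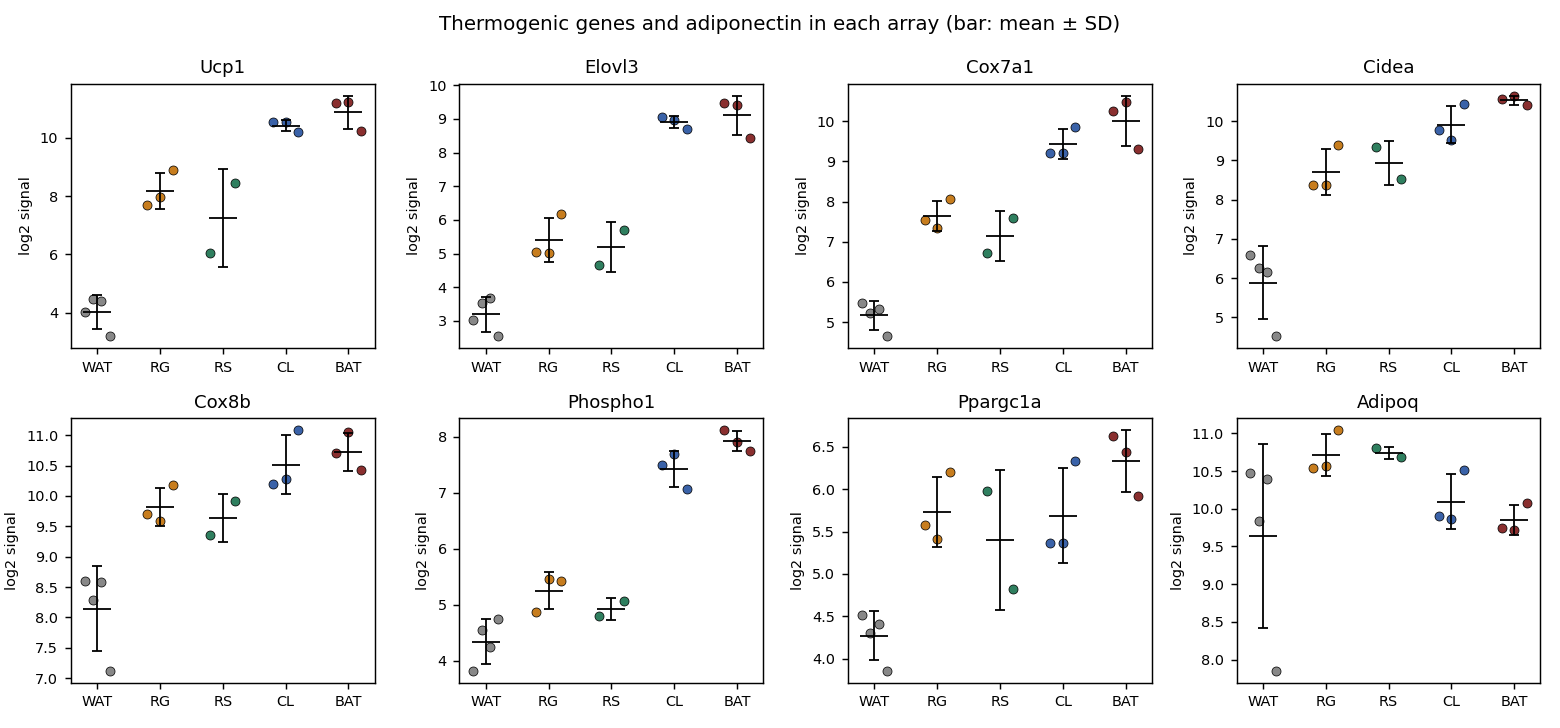
Log2 expression of 8 adipocyte genes on each array, with the group mean and SD (n = 4 WAT, 3 RG, 2 RS, 3 CL and 3 BAT). Ucp1 ranges from 3.20 to 4.47 in WAT, from 10.19 to 10.53 in CL, and is 6.05 and 8.43 in the RS arrays.

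CL against WAT sets UCP1-positive cells of inguinal fat after beta-adrenergic stimulation against white cells of untreated fat. Ucp1 was 83.9-fold higher in CL (log2 difference 6.39 ± 0.465, SE, n = 3 and 4, adjusted p = 3.04e-06), Elovl3 was 52.5-fold higher and Cox7a1 19.2-fold. Cidea rose 16.3-fold, Slc27a2 11.5-fold, Otop1 9.87-fold, and Phospho1, a phosphatase of phosphocholine, 8.44-fold. Serpina1b, a secreted protease inhibitor, rose 9.71-fold with an SD of 1.84 log2 units among the CL arrays. Of 29 thermogenic genes, 23 rose and none fell (23 adjusted over the list alone), with an adjusted p = 2.15e-16, and adjusted p = 0.162 with an estimated correlation. Fatty acid oxidation rose in 21 of 25 genes (21 adjusted over the list alone), with an adjusted p = 2.84e-10, and adjusted p = 0.249 with an estimated correlation. Its examples were Acaa2 and Hadha, enzymes of beta-oxidation, higher by 2.08 and 1.80 log2 units, and Slc25a20, the carnitine carrier of mitochondria, higher by 2.30. The TCA cycle rose in 19 of 22 genes (19 adjusted over the list alone), with an adjusted p = 2.3e-09, and adjusted p = 0.31 with an estimated correlation. In oxidative phosphorylation 59 of 69 rose (60 adjusted over the list alone), with an adjusted p = 8.78e-19, and adjusted p = 0.3 with an estimated correlation.

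Macrophage and stromal markers were lower in CL than in WAT. Ptafr, the receptor of platelet-activating factor, fell 11.4-fold, Cd209g 11.3-fold, Cd209f 10.6-fold, Cd209d 9.51-fold, Plac8 9.56-fold, Siglec1, a lectin of macrophages, 9.95-fold, the chemokine Ccl3 10.2-fold and Sfrp4 10.0-fold. All 22 macrophage markers fell (22 adjusted over the list alone), with an adjusted p = 2.01e-20, and adjusted p = 0.162 with an estimated correlation. Stromal and preadipocyte markers fell in 11 of 20 (14 adjusted over the list alone), with an adjusted p = 4.96e-08, and adjusted p = 0.249 with an estimated correlation. None of the 20 endothelial markers was called by limma (0 adjusted over the list alone), with a median log2 difference of 0.25 and an adjusted p = 0.875, and adjusted p = 0.983 with an estimated correlation. Of 21 genes of the beta-adrenergic and cAMP response, 5 rose and 6 fell (6 and 8 adjusted over the list alone), with an adjusted p = 0.0527, and adjusted p = 0.31 with an estimated correlation. Among them Pde4d, which degrades cAMP, rose by 0.99 log2 units, and the cytokine Il6 fell by 2.16. Mature adipocyte genes rose in 8 of 27 (11 adjusted over the list alone), with an adjusted p = 9.44e-05, and adjusted p = 0.484 with an estimated correlation. In all 6350 probe sets changed, 3838 higher and 2512 lower, with 2461 called in the blocked fit and 4916 without both WAT 4 and RS 3. Without CL 4 the count was 3560, the median of all probe sets lay at 0.13, and median centring brought the share called higher from 60.4% to 50.7%. The genes called higher held 481 olfactory and vomeronasal receptor probe sets, against 95 after quantile normalization.

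RS against WAT asks the same of the UCP1-positive cells found after roscovitine. Ucp1 was 9.30-fold higher in RS (log2 difference 3.22 ± 0.527, SE, n = 2 and 4, adjusted p = 0.00139), at 8.43 in RS 4 and 6.05 in RS 3 against 4.47 or less in WAT. Cidea rose 8.28-fold, Otop1 4.60-fold, Elovl3 3.99-fold and Cox7a1 3.94-fold. Gsdma2, a gasdermin, rose from levels below the 10th percentile of each WAT array. Ntrk3, a neurotrophin receptor, rose 4.31-fold, Higd1c 4.08-fold and Sorcs2, a receptor of the sortilin family, 3.96-fold. Without RS 3 the calls of Otop1, Ntrk3 and Sorcs2 were lost, with adjusted p-values of 0.0565, 0.202 and 0.214, and without RS 4 that of Elovl3 was lost (adjusted p = 0.0637). Of 29 thermogenic genes, 16 rose and 1 fell (18 and 1 adjusted over the list alone), with an adjusted p = 1.82e-06, and adjusted p = 0.453 with an estimated correlation. The blocked fit called 7 of them higher, and 8 were called without both WAT 4 and RS 3. Fatty acid oxidation rose in 6 of 25 genes and fell in 1 (10 and 2 adjusted over the list alone), with an adjusted p = 0.00719, and adjusted p = 0.557 with an estimated correlation. Cpt1a, the gatekeeper of fatty acid entry into mitochondria, was the gene that fell, by 1.67 log2 units. Without both WAT 4 and RS 3 none of the 25 was called by limma. Oxidative phosphorylation rose in 14 of 69 (5 adjusted over the list alone), with an adjusted p = 9.26e-07, and adjusted p = 0.557 with an estimated correlation.

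Macrophage markers were again lower. All 22 fell in RS (22 adjusted over the list alone), with a median log2 difference of -2.92 and an adjusted p = 2.96e-22, and adjusted p = 0.207 with an estimated correlation. Ms4a6d fell 18.1-fold, Cd209f 16.8-fold, Folr2, a folate receptor of macrophages, 16.6-fold, Cpa3, a protease of mast cells, 15.1-fold, Ccl8 14.9-fold, Igsf6 14.5-fold, Cd209g 14.3-fold and Lilrb4a, an inhibitory receptor of leukocytes, 13.2-fold. Stromal and preadipocyte markers fell in 15 of 20 genes (16 adjusted over the list alone), with an adjusted p = 3.72e-08, and adjusted p = 0.377 with an estimated correlation. Endothelial markers fell in 10 of 20 (16 adjusted over the list alone), with an adjusted p = 2.12e-07, and adjusted p = 0.453 with an estimated correlation. Their mean level was -2.10 in RS 3 and -0.04 in RS 4, and without both WAT 4 and RS 3 the count was 1. Cell cycle genes fell in 9 of 40 (9 adjusted over the list alone), with an adjusted p = 0.00261, and adjusted p = 0.387 with an estimated correlation. Of the 40, only 3 had a mean over 5 across all arrays, so few genes of this list had a strong signal. Examples were Cenpa, a centromeric histone, 2.30-fold lower, and Mki67, a proliferation marker, lower by 1.25 log2 units. The same list also fell in 8 genes and rose in 3 in BAT (the same counts adjusted over the list alone, adjusted p = 0.00124, and adjusted p = 0.189 with an estimated correlation). In RG it fell in 6 and rose in 1 (8 and 1 adjusted over the list alone, adjusted p = 4.95e-05, and adjusted p = 0.22 with an estimated correlation). In CL it fell in 3 and rose in 2 (2 and 2 adjusted over the list alone, adjusted p = 0.053, and adjusted p = 0.342 with an estimated correlation). Its mean level was highest in WAT 4, at 0.387, and lay at -0.131 and -0.092 in RS against 0.056 to 0.106 in CL and -0.198 to -0.052 in RG. Cenpa was also lower in RS than in CL (adjusted p = 0.00455), BAT (0.0189) and RG (0.0493), all calls that the blocked fit lost. Of 22 cyclin-dependent kinases and partners, 5 fell and 1 rose (the same counts adjusted over the list alone), with an adjusted p = 0.0185, and adjusted p = 0.219 with an estimated correlation. Among them Ccnd1, cyclin D1, fell by 1.28 log2 units and Cdkn1a, a kinase inhibitor, by 1.33. In BAT 6 of the 22 fell and 1 rose (the same counts adjusted over the list alone, adjusted p = 0.00612, and adjusted p = 0.134 with an estimated correlation). Mature adipocyte genes rose in 9 of 27 (15 adjusted over the list alone), with an adjusted p = 5.9e-06, and adjusted p = 0.518 with an estimated correlation. Without both WAT 4 and RS 3, 5 of them were called.

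In all 5387 probe sets changed in RS, 2786 higher and 2601 lower. The blocked fit called 2052, and 2438 were called without both WAT 4 and RS 3. Leaving out RS 3 gave 3468 and leaving out RS 4 gave 2951. The median of all probe sets lay at 0.14, and median centring brought the share called higher from 51.7% to 39.2%. The genes called higher held 339 olfactory and vomeronasal receptor probe sets, against 55 after quantile normalization.

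RG against WAT covers the UCP1-positive cells found after the PPARG agonist. Ucp1 was 17.8-fold higher in RG (log2 difference 4.15 ± 0.465, SE, n = 3 and 4, adjusted p = 0.00016), Cidea 7.11-fold, Otop1 5.91-fold, Cox7a1 5.57-fold and Elovl3 4.66-fold. Gys2, a glycogen synthase, rose 4.33-fold, Arxes1, an adipocyte gene of the X chromosome, 4.26-fold, Ces1f, a carboxylesterase, 3.67-fold, and Lep, which encodes leptin, 3.32-fold. Of 29 thermogenic genes 17 rose (19 adjusted over the list alone), with an adjusted p = 5.25e-12, and adjusted p = 0.223 with an estimated correlation. PPARG agonist targets rose in 11 of 21 genes and fell in 1 (14 and 1 adjusted over the list alone), with an adjusted p = 7.04e-06, and adjusted p = 0.299 with an estimated correlation. Of the 21, 18 were also in another list, such as Ucp1 and Cidea of the thermogenic one, so this rise is not a separate result. The PPARG target list rose in 10 genes in CL and 8 in RS, and 0 of its members differed between RS and RG by limma. In CL against RG 2 members were higher in CL, Ucp1 (adjusted p = 0.0307) and Slc25a20 (adjusted p = 0.0298), and neither was called in the blocked fit. Mature adipocyte genes rose in 11 of 27 (25 adjusted over the list alone), among them Pparg itself by 0.91 log2 units, with an adjusted p = 2.46e-09, and adjusted p = 0.352 with an estimated correlation. WAT 4 stood apart in this list, at -1.55 against -0.59 to -0.08 in the other WAT arrays, and without both WAT 4 and RS 3 its median in RG went from 0.91 to 0.53, with 10 genes higher. Fatty acid oxidation rose in 18 of 25 genes and fell in 2 (22 and 2 adjusted over the list alone), with an adjusted p = 3.85e-08, and adjusted p = 0.33 with an estimated correlation. Oxidative phosphorylation rose in 35 of 69 (52 adjusted over the list alone), with an adjusted p = 1.12e-16, and adjusted p = 0.33 with an estimated correlation.

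Among the genes lower in RG, the mast cell protease Cpa3 fell 23.8-fold, and Tpsb2, a tryptase, 12.7-fold. Mcpt4, a chymase, fell to a mean below that of the 10th percentiles of the RG arrays. Ccl3 fell 13.2-fold, Cd209f 12.8-fold, Ms4a6b 11.5-fold, and Ccl8 and Cd209g 8.89-fold each. Macrophage markers fell in 20 of 22 (22 adjusted over the list alone), with an adjusted p = 1.65e-24, and adjusted p = 0.156 with an estimated correlation. Endothelial markers fell in 2 of 20 (3 adjusted over the list alone), with an adjusted p = 2.53e-07, and adjusted p = 0.399 with an estimated correlation. Their mean level was -1.16 in RG 2 and -0.93 in RG 3 but 0.12 in RG 4, inside the WAT range of -0.41 to 0.91. In all 2882 probe sets changed, 1308 higher and 1574 lower, with 1071 called in the blocked fit, 1991 without both WAT 4 and RS 3, and a median of all probe sets of 0.10. Ces1f, Gys2, Arxes1 and Lep lost their calls without at least 1 array, with adjusted p-values up to 0.155, 0.0512, 0.0752 and 0.121. Low values in WAT 4 enlarge their folds. Ces1f was 5.02 there against 7.43 to 8.10 in the other WAT arrays, and Gys2 4.13 against 5.91 to 6.60. Arxes1 was 4.52 in WAT 4 against 6.28 to 6.68, and Lep 4.84 against 6.62 to 7.29. The count fell to 1044 without RG 4, 1215 without RG 2, 1555 without WAT 4, 1773 without WAT 2 and 1886 without RG 3. The genes called higher held 111 olfactory and vomeronasal receptor probe sets, against 22 after quantile normalization.

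**Figure D2:**
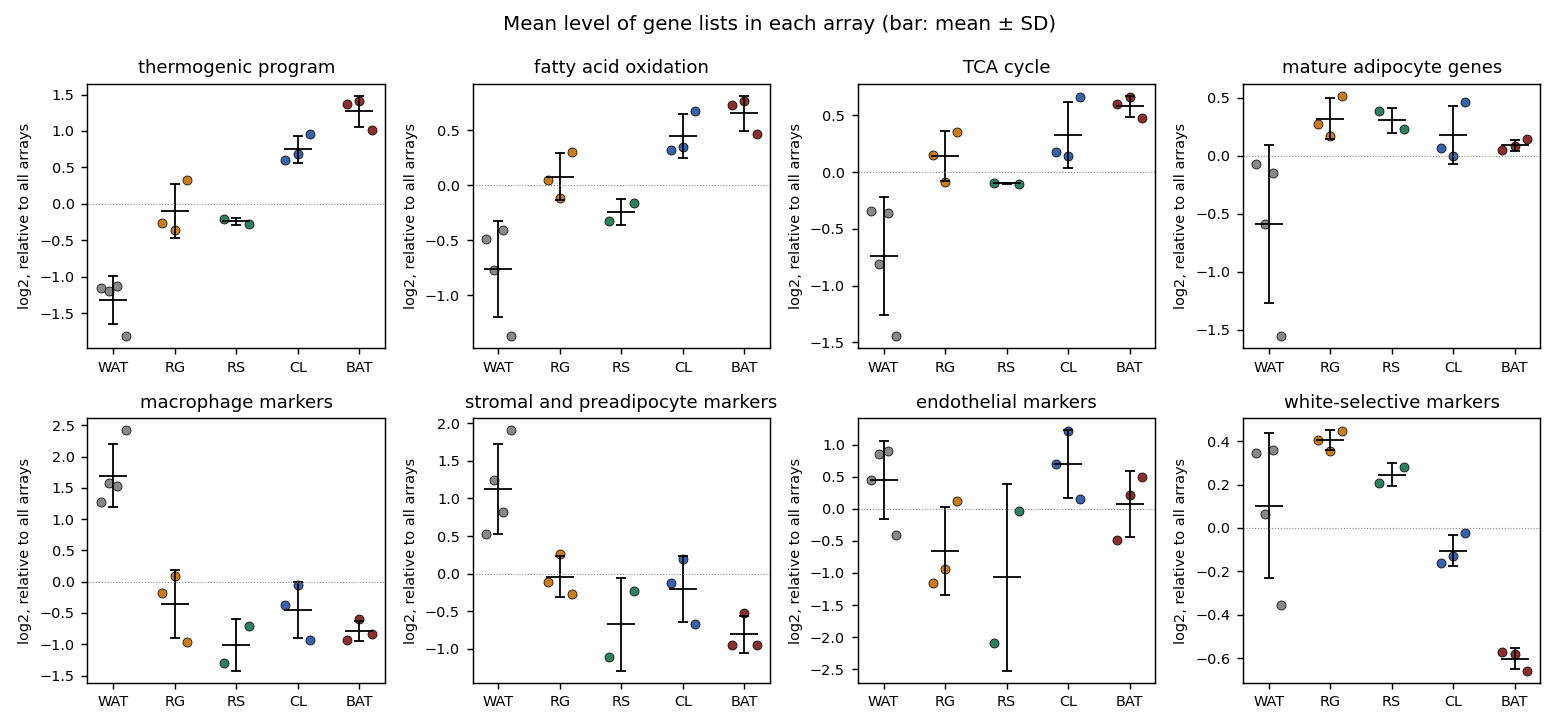
Mean log2 level of 8 gene lists on each array relative to the mean of all 15 arrays, with groups ordered WAT, RG, RS, CL and BAT. Macrophage markers lie between 1.27 and 2.42 in WAT and at or below 0.09 elsewhere, and endothelial markers reach -2.10 in RS 3.

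**Figure D3:**
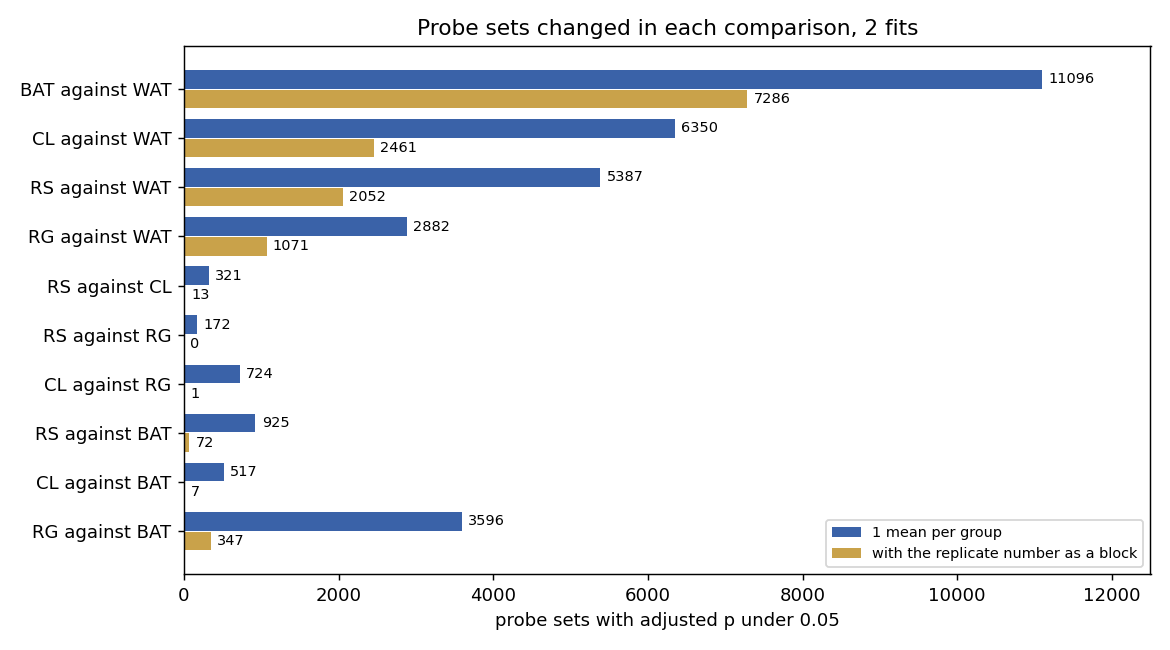
Number of probe sets called at an adjusted p under 0.05 in each of the 10 comparisons, with 1 mean per group and with the replicate number as a block. Counts are 11096 and 7286 in BAT against WAT, and 172 and 0 in RS against RG.

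The position index asks how far each treated group lies from WAT (0) towards BAT (1) over the 11096 genes called between them. It was 0.677 ± 0.0975 in CL (SD, n = 3), 0.680 ± 0.0248 in RS (SD, n = 2) and 0.512 ± 0.0726 in RG (SD, n = 3), with WAT arrays between -0.209 and 0.127. RS and CL did not differ (difference 0.00271, two-sided exact permutation p = 0.9), nor did RS and RG (0.168, exact permutation p = 0.2) or CL and RG (0.166, exact permutation p = 0.1). The smallest p these tests can give is 0.1, and the adjusted p-values over the 9 index tests were 0.3 or higher, so none can pass the threshold. Over the genes higher in BAT alone, an alternative chosen after seeing the data, the index was 0.633 in CL, 0.548 in RS and 0.398 in RG. These genes carry part of the scale shift between arrays, since the olfactory and vomeronasal receptor probe sets, 776 of them called higher in BAT, had medians of 0.48 in CL, 0.44 in RS and 0.27 in RG against WAT. Over the genes lower in BAT it was 0.714 in CL, 0.791 in RS and 0.606 in RG. Every CL, RS and RG array lay farther towards BAT over the genes lower in BAT than over those higher in BAT, for example 0.846 against 0.520 in RS 3, 0.626 against 0.379 in RG 2 and 0.595 against 0.583 in CL 3. The genes lower in BAT held all 22 macrophage markers and most stromal and preadipocyte markers. How much of the index over the lower genes, or over all genes, follows the sorting gate of WAT was not tested.

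**Figure D4:**
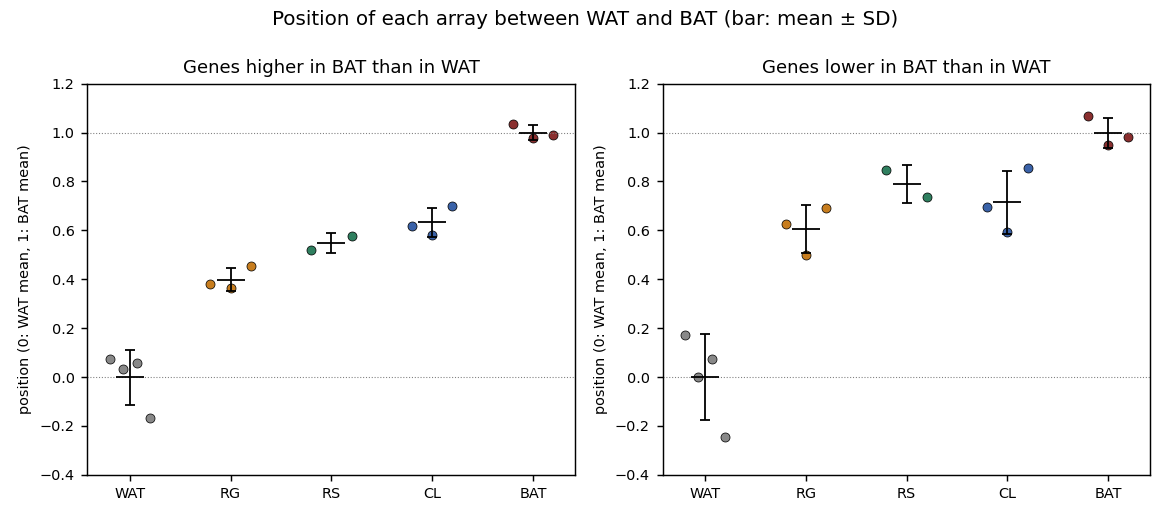
Position index of each array on the line from the mean of the WAT arrays (0) to the mean of the BAT arrays (1). It is shown separately over the genes higher and the genes lower in BAT, a split chosen after seeing the data. Over the higher genes CL averages 0.633, RS 0.548 and RG 0.398, and over the lower genes 0.714, 0.791 and 0.606.

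The overlap of the 3 treated groups asks which changes they share. Against WAT, 284 probe sets were higher and 953 lower in CL, RS and RG alike, 1237 in all, and 16 were called in opposite directions. Of these, 256 and 934 were also higher and lower in BAT. The blocked fit gave 490 and leaving out WAT 4 and RS 3 together gave 522. Single arrays moved the count to 583 without RG 4, 648 without RG 2, 677 without WAT 4 and 790 without WAT 2. All 3 comparisons use the same WAT arrays, so part of the overlap comes from them. CL and RS shared 1291 higher and 1479 lower calls, where 424 and 259 would be expected of independent lists. Log2 differences in CL and RS correlated across genes at 0.758, against 0.377 in simulations of independent noise with a shared simulated WAT group. The correlation was 0.662 when the measured WAT arrays were divided 2 and 2 between CL and RS, which left a mean of 898 shared calls. The simulated value follows from the group sizes, so it cannot show what the measured WAT arrays add to the correlation. The covariance of the differences in CL and RS exceeded the simulated one by 0.265, with the same limit. CL and RG shared 688 higher and 1128 lower calls (199 and 157 for independent lists), with a correlation of 0.742 (0.427 simulated, 0.625 with WAT divided), a covariance excess of 0.202 and 498 shared calls with WAT divided. RS and RG shared 407 and 1214 (145 and 162), with a correlation of 0.771 (0.376 simulated, 0.663 divided), an excess of 0.235 and 489.5 shared calls with WAT divided. Genes are not independent replicates, and with 3 comparisons and WAT divided in 2 the 3-way overlap has no divided value.

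RS against CL compares the cells of both treatments directly. Elovl3 was 13.2-fold lower in RS (log2 difference -3.72 ± 0.423, SE, n = 2 and 3, adjusted p = 0.00182), Ucp1 9.02-fold lower (adjusted p = 0.0202), Phospho1 5.62-fold and Cox7a1 4.86-fold. The Ucp1 difference was -1.98 log2 units without RS 3 (adjusted p = 0.0989) and -4.36 without RS 4. Thermogenic genes fell in 10 of 29 (14 adjusted over the list alone), with a median log2 difference of -0.98 and an adjusted p = 1.21e-11, and adjusted p = 0.555 with an estimated correlation. Acot11 was lower by 1.72 log2 units and Acaa2 by 1.29. In RS 3, 24 of the 29 lay below the CL mean, and in RS 4, 27. Fatty acid oxidation fell in 3 of 25 (11 adjusted over the list alone), led by Acsl5, an acyl-CoA synthetase, 2.82-fold lower, with an adjusted p = 2.81e-08, and adjusted p = 0.756 with an estimated correlation. Cidea, Cox8b, Dio2, Ppargc1a and Prdm16 did not pass the test, with log2 differences between -0.98 and 0.13.

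Vessel genes were lower beside them. Kdr, a VEGF receptor, was 6.13-fold lower and Gpihbp1, which anchors lipoprotein lipase to capillaries, 5.92-fold. Endothelial markers fell in 4 of 20 (17 adjusted over the list alone), with an adjusted p = 1.21e-11, and adjusted p = 0.756 with an estimated correlation. Both genes were lowest in RS 3, at 4.86 and 4.36 against 6.96 and 6.82 in RS 4, and without both WAT 4 and RS 3 none of the 20 was called by limma. Rasgrp3, an activator of Ras, was 4.96-fold lower and Gnb4, a G protein subunit, 4.90-fold. Macrophage markers fell in 1 of 22 (1 adjusted over the list alone), with an adjusted p = 0.00386, and adjusted p = 0.792 with an estimated correlation. Higher in RS were Higd1c (3.39-fold), Alkal2, a ligand of the kinase ALK (3.34-fold), Klra7, a lectin receptor of natural killer cells (3.16-fold), Cmklr1, the chemerin receptor (2.92-fold), Rrp7a (2.79-fold), Ifrd1 (2.76-fold) and the imprinted gene Peg3 (2.74-fold). Rnd3 was higher too, at 5.64 and 5.52 in RS against 3.92 to 4.30 in CL.

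Of 25206 probe sets, 321 changed between RS and CL, 120 higher and 201 lower, or 121 without both WAT 4 and RS 3, and quantile normalization brought the share called higher from 37.4% to 49.7%. The count was 41 without CL 3, 83 without RS 3, 105 without CL 1, 110 without CL 4 and 566 without RS 4. The blocked fit called 13. Of the genes named here these held only Elovl3 and Phospho1 (adjusted p = 0.0257 each), and not, for example, Ucp1 (adjusted p = 0.116), Cox7a1 (0.0987), Kdr (0.178), Gpihbp1 (0.179) or Rrp7a (0.0833). Of the genes with the largest differences, only Elovl3, Phospho1 and Rrp7a kept their calls whichever array was left out.

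RS against RG compares the cells found after roscovitine and after the PPARG agonist. None of the 29 thermogenic genes differed by limma (0 adjusted over the list alone), with a median log2 difference of -0.25 and an adjusted p = 0.216, and adjusted p = 0.968 with an estimated correlation. Ucp1 differed by -0.94 ± 0.556 (log2, SE, n = 2 and 3, adjusted p = 0.39), which leaves a wide margin rather than showing equal levels. None of the 15 marker genes passed the test. Serpina3f, a protease inhibitor, was 4.80-fold lower in RS, Eif2s3y, a Y-linked translation factor, 4.60-fold, Cldn34c2 3.28-fold, Tlcd3a 3.20-fold, Grb14, an adaptor of the insulin receptor, 3.04-fold, Rabif 2.87-fold, and H2bc7, a histone, 2.80-fold. Eif2s3y was 2.55 in RS 3 and 3.92 in RS 4. Higd1c was 4.24-fold higher, Krtap5-2, a keratin-associated protein, 3.34-fold, Btbd35f28 2.73-fold and Slc7a14 2.69-fold. Cyp3a41b, Chil4, Acnat1 and Krtap9-3 were also called higher and Tas2r108 lower, but lay below the 10th percentile of every array of RG, or of RS for Tas2r108, so no fold is given. Each of these 16 genes lost its call without at least 1 array, with adjusted p-values up to 0.189. Macrophage markers lay lower in RS by a median of 0.67 log2 units, with 0 of 22 called by limma (2 lower adjusted over the list alone) and an adjusted p = 0.00108, and adjusted p = 0.968 with an estimated correlation. In all 172 probe sets changed, 87 higher and 85 lower, and 4676 had an unadjusted p under 0.05. The blocked fit of limma called 0, with 2761 at an unadjusted p under 0.05, and 406 were called without both WAT 4 and RS 3. The count was 8 without RG 3, 13 without RG 4, 17 without RG 2, 35 without RS 4 and 308 without RS 3, and median centring moved the share called higher from 50.6% to 32.5%.

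In CL against RG, Elovl3 was 11.3-fold higher in CL (log2 difference 3.49 ± 0.378, SE, n = 3 and 3, adjusted p = 0.00145), Cpa3 6.90-fold, and Ucp1 4.71-fold. Zfp979 was also called higher, from levels below the 10th percentile of each RG array. Serpina3f was 5.86-fold lower, Celsr2, a cadherin, 4.59-fold, the imprinted gene Nnat 4.21-fold and Cers6, a ceramide synthase, 3.90-fold. Thermogenic genes rose in 9 of 29 (13 adjusted over the list alone), with an adjusted p = 1.94e-08, and adjusted p = 0.673 with an estimated correlation. Endothelial markers rose in 1 of 20 (13 adjusted over the list alone), with an adjusted p = 5.95e-08, and adjusted p = 0.827 with an estimated correlation. Their mean level was -1.16 in RG 2 and -0.93 in RG 3, but 0.12 in RG 4, beside 0.16 in CL 4. It was 0.70 in CL 1 and 1.22 in CL 3. In all 724 probe sets changed, 416 higher and 308 lower, or 1189 without both WAT 4 and RS 3, and centring moved the share called higher from 57.5% to 43.9%. Of these 8 genes, only Elovl3 kept its call whichever array was left out. The blocked fit called 1, Acsl5, and the count was 28 without RG 3, 32 without RG 2, 199 without CL 1, 229 without CL 4, 295 without RG 4 and 347 without CL 3.

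Set against brown cells, CL came closest in thermogenic genes. Between CL and BAT, Ucp1 differed by -0.46 ± 0.497 (log2, SE, n = 3 and 3, adjusted p = 0.67), and thermogenic genes fell in 3 of 29 (6 adjusted over the list alone), with an adjusted p = 6.21e-05, and adjusted p = 0.548 with an estimated correlation. H2-DMb2 was 34.1-fold higher in CL, with BAT arrays between 2.03 and 5.05, Mup3, a urinary protein, 10.8-fold, Alb, albumin, 5.28-fold and Pcdha3, a protocadherin, 3.92-fold. Lymphocyte markers rose in 2 of 22 (11 adjusted over the list alone), Cd3e of T cells and Cd79b of B cells, with an adjusted p = 9.24e-07, and adjusted p = 0.548 with an estimated correlation. Their mean level was 0.58 in CL 1 and 0.75 in CL 3 but -0.27 in CL 4, against -0.75 to -0.31 in BAT. Macrophage markers rose in 2 of 22 (2 adjusted over the list alone), Aif1 and Cd163, with an adjusted p = 0.0156, and adjusted p = 0.797 with an estimated correlation. Their mean level was -0.370 in CL 1 and -0.051 in CL 3, but -0.928 in CL 4, inside the BAT range of -0.930 to -0.603. Kng2 was 8.22-fold lower, Sorcs2 4.07-fold and Zfp991 3.44-fold. Magea1 was also called lower, to levels below the 10th percentile of each CL array, so no fold is given. Mup3, Alb, Sorcs2 and Zfp991 lost their calls without at least 1 array, with adjusted p-values up to 0.118, 0.0887, 0.122 and 0.16. In all 517 probe sets changed, 160 higher and 357 lower, and 846 were called without both WAT 4 and RS 3. The blocked fit called 7, of the genes named here only Kng2 and Magea1. The share called higher went from 30.9% to 42.4% after quantile normalization, and the count was 122 without CL 3, 128 without CL 1, 248 without BAT 1, 250 without CL 4 and 285 without BAT 4.

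In RS against BAT, Elovl3 was 15.1-fold lower in RS, Ucp1 12.4-fold (log2 difference -3.63 ± 0.556, SE, n = 2 and 3, adjusted p = 0.00355), Slc27a2 11.6-fold and Kng2 8.99-fold. The Ucp1 difference was -2.44 log2 units without RS 3 and -4.82 without RS 4. Thermogenic genes fell in 13 of 29 (23 adjusted over the list alone), with an adjusted p = 8e-19, and adjusted p = 0.141 with an estimated correlation. White-selective markers rose in 5 of 20 (8 adjusted over the list alone), among them Dpt, a matrix protein, by 1.16 log2 units, with an adjusted p = 3.66e-09, and adjusted p = 0.0614 with an estimated correlation. Xist, the RNA of the inactive X chromosome, was 12.4-fold higher, at 7.83 in RS 3 and 3.95 in RS 4, Alb 8.93-fold, Cmklr1 7.62-fold and Vnn3 5.92-fold. Xist, Alb and Vnn3 lost their calls without at least 1 array, with adjusted p-values up to 0.357, 0.0929 and 0.169. In all 925 probe sets changed, 334 higher and 591 lower, with 72 in the blocked fit, with Ucp1 and Elovl3 but not Xist, Alb or Vnn3 among them, and 496 without both WAT 4 and RS 3. The count was 370 without RS 3 and 475 without BAT 3.

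In RG against BAT, Slc27a2 was lower in RG by 3.70 log2 units, Elovl3 12.9-fold lower, Acot11 10.5-fold, Kng2 10.3-fold and Ucp1 6.48-fold (log2 difference -2.70 ± 0.497, SE, n = 3 and 3, adjusted p = 0.00414). Thermogenic genes fell in 18 of 29 (23 adjusted over the list alone), with an adjusted p = 5.01e-12, and adjusted p = 0.331 with an estimated correlation. White-selective markers rose in 13 of 20 (14 higher and 1 lower adjusted over the list alone), with an adjusted p = 1.9e-08, and adjusted p = 0.0723 with an estimated correlation. H2-DMb2 was 16-fold higher, Alb 8.42-fold, Nnat 6.93-fold and Hoxc8, a positional transcription factor, 5.92-fold. In all 3596 probe sets changed, 1474 higher and 2122 lower, with 347 in the blocked fit and 4519 without both WAT 4 and RS 3. The share called higher went from 41.0% to 59.3% after median centring, and the count was 1593 without RG 3, 1700 without RG 2, 2014 without RG 4 and 2295 without BAT 1.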

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

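All tests of explanations below were chosen after the result was seen, and the search for arrays far from their group used a fixed rule.

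Macrophage markers were higher in WAT than in every UCP1-positive group, with at least 90.9% of the 22 measured markers called lower in BAT, CL, RS and RG. Folr2 stood at 9.29 in WAT and 6.71 in CL, and C1qa, a complement gene of macrophages, at 9.16 and 6.68. A lower adipocyte share in WAT that raised all other cell types alike is argued against by the endothelial markers for CL only. There the macrophage level minus the endothelial level was lower than in WAT by 2.39 log2 units (-2.39, SE 0.629). The endothelial level was -2.10 and -0.04 in RS and -1.16 to 0.12 in RG, against -0.41 to 0.91 in WAT. For RS and RG this explanation was not tested. Treatment alone is argued against by untreated BAT, where all 22 were lower too (Folr2 6.02, C1qa 6.01). Macrophages that pass the UCP1-negative gate could give such values, and the gate differs between WAT and all other groups, so gate and cell type cannot be separated, and how much of the overlap against WAT comes from this is open.

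Thermogenic genes were lower in RS than in CL, with 10 of 29 called (1 in the blocked fit), a median log2 difference of -0.98 and an adjusted p = 0.555 with an estimated correlation. Admixture of cells like those of the WAT sort could lower them, and at the median share of 24.1% of the CL signal, over the 21 thermogenic genes raised at least 2-fold in CL, would have raised macrophage markers by 1.86 log2 units, but these lay at -0.56 (SE 0.398) relative to CL. The share ranged from 1.04% to 78.9% over these genes, and how much of that range is spread between the 2 RS arrays was not tested. The macrophage values argue only against admixture that brings the macrophage signal of the WAT sort. White adipocytes without that signal would not raise these markers, and their admixture was not tested. The mean level of white-selective markers was 0.207 in RS 3 and 0.282 in RS 4. It was -0.159 to -0.021 in CL and -0.357 to 0.360 in WAT. The array RS 3 alone does not carry the pattern, as the median log2 difference from the CL mean was -0.89 in RS 4 and -0.78 in RS 3. With 2 arrays and no untreated UCP1-positive cells, a weaker response and a different sorted fraction remain possible.

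Same-numbered arrays deviated from their group means in opposite directions, with correlations from -0.881 to -0.0498 across probe sets in 24 pairs. The median p of an F test of the number was 0.932, where random reassignments of the numbers gave a median of 0.509, and 0 of 100 reached the real value (highest 0.745). Numbers unrelated to the arrays are argued against by this, and removal of a number effect before deposit could leave such a mark. In simulations with such a removal 11.8% of unchanged genes had an unadjusted p under 0.05 without the block and 4.96% with it, and false calls averaged 13.05 and 0.09. The series does not say what was done, and genes called only without the block, such as Ucp1 between RS and CL (adjusted p = 0.0202 without it and 0.116 with it), stay open.

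Other divisions of the same arrays were counted for comparisons of groups of at least 3 arrays, and not for those with RS. For BAT against WAT the real division was 1 of 35 to reach its count of 11096, with 3892 as the highest other. For CL against WAT it was 1 of 35 (6350, highest other 1314), and for RG against WAT 1 of 35 (2882, highest other 1020). Comparisons of 3 with 3 arrays have 10 divisions, too few for a share under 0.05. The real one was 1 of 10 in CL against RG (724, highest other 0), 1 of 10 in CL against BAT (517, highest other 1) and 1 of 10 in RG against BAT (3596, highest other 0).

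Of 129 sets of 4 WAT values searched for 1 value apart from the others, 8 (6.20%) had one, where about 1 in 20 is expected by chance. WAT 4 held 7 of them. Cd209g was 7.02 there against 7.63 to 7.71. Tmem26, a surface marker of beige cells, was 6.14 against 4.11 to 4.27. The chemokine Ccl3 was 8.81 against 7.04 to 7.27, and Cers6 was 7.82 against 6.77 to 6.85. The mean level of thermogenic genes was -1.81 against -1.19 to -1.13. That of skeletal muscle markers was -0.412 against -0.219 to -0.196. The array median was 3.33 against 3.36 in the others. In WAT 2 the mean level of genes of the beta-adrenergic and cAMP response was 0.261 against 0.0282 to 0.0591. The cause was not tested.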

How the results depend on the processing

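Leaving out WAT 4 and RS 3 together and the index over genes of 1 direction were chosen after the result was seen. With the replicate block, 62 of 255 named gene results lost a call, 3 moved and 190, called or not, stayed as they were. Array weights took 33 calls away, a fit of only the 2 groups compared 42, leaving out WAT 4 and RS 3 together 30, and leaving out 1 array in turn 219 of all gene results so tested, while an intensity trend with robust estimation changed none. Of 370 list results 212, called or not, stayed as they were and 158 lost a call with an estimated correlation, 84 lost it under fry and 4 under the block. The WAT split was not computable for the overlap of 3 comparisons.

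BAT against WAT gave 11096 genes, 7286 with the block, 6220 after quantile normalization again, 5273 without the dimmest 50%, 3248 at 2-fold or more, and 8585 to 10173 with 1 array left out. CL against WAT gave 6350, 2461 with the block, 3152 after quantile normalization, 3275 without the dimmest 50%, 1743 at 2-fold, and 3560 to 5519 with 1 array left out. RS against WAT gave 5387, 3433 in the fit of 2 groups, 2052 with the block, 2455 after quantile normalization, 2944 without the dimmest 50%, 2376 with weights, 2438 without both WAT 4 and RS 3, 1958 at 2-fold, 8287 at an adjusted p under 0.1, and 2951 to 5008 with 1 array left out (3468 without RS 3). RG against WAT gave 2882, 1071 with the block, 6509 with weights, 1197 at 2-fold, 4736 at an adjusted p under 0.1, and 1044 to 2783 with 1 array left out (1215 without RG 2, 1555 without WAT 4, 1773 without WAT 2, 1886 without RG 3).

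RS against CL gave 321, 4 in the fit of 2 groups, 13 with the block, 20 with weights, 121 without both WAT 4 and RS 3, 957 at an adjusted p under 0.1, and 41 to 566 with 1 array left out (83 without RS 3, 105 without CL 1, 110 without CL 4). RS against RG gave 172, 0 in the fit of 2 groups, 0 with the block, 44 after quantile normalization, 99 without the dimmest 25% and 82 without the dimmest 50%, 9 with weights, 406 without both WAT 4 and RS 3, 109 at 2-fold, 952 at an adjusted p under 0.1, and 8 to 308 with 1 array left out (13 without RG 4, 17 without RG 2, 35 without RS 4). CL against RG gave 724, 1 with the block, 442 after quantile normalization, 448 without the dimmest 25% and 343 without the dimmest 50%, 2615 with weights, 1189 without both WAT 4 and RS 3, 298 at 2-fold, 1672 at an adjusted p under 0.1, and 28 to 347 with 1 array left out (32 without RG 2, 199 without CL 1, 229 without CL 4, 295 without RG 4).

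RS against BAT gave 925, 60 in the fit of 2 groups, 72 with the block, 595 without the dimmest 50%, 128 with weights, 496 without both WAT 4 and RS 3, 510 at 2-fold, 1901 at an adjusted p under 0.1, and 370 to 894 with 1 array left out (475 without BAT 3). CL against BAT gave 517, 41 in the fit of 2 groups, 7 with the block, 227 without the dimmest 25% and 106 without the dimmest 50%, 846 without both WAT 4 and RS 3, 189 at 2-fold, 1474 at an adjusted p under 0.1, and 122 to 512 with 1 array left out (128 without CL 1, 248 without BAT 1, 250 without CL 4, 285 without BAT 4). RG against BAT gave 3596, 347 with the block, 2021 after quantile normalization, 2279 without the dimmest 25% and 1688 without the dimmest 50%, 963 at 2-fold, 5880 at an adjusted p under 0.1, and 1593 to 3077 with 1 array left out (1700 without RG 2, 2014 without RG 4, 2295 without BAT 1).

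The position of RS was 0.680, 0.714 without the dimmest 50%, over genes higher in BAT 0.548 and lower in BAT 0.791, and 0.643 to 0.715 with 1 array left out (0.651 without BAT 3, 0.652 without BAT 4). That of RG was 0.512, over genes higher in BAT 0.398 and lower in BAT 0.606, and 0.468 to 0.553 with 1 array left out, and that of CL was 0.624 to 0.722. The overlap of CL, RS and RG against WAT was 1237, 2111 at an adjusted p under 0.1, 522 without both WAT 4 and RS 3, 490 with the block, and 583 to 1322 with 1 array left out (648 without RG 2, 677 without WAT 4, 790 without WAT 2). With WAT split 2 and 2, CL and RS shared 898 genes, CL and RG 498 and RS and RG 489.5.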

Other observations

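The test of sex-linked genes below was chosen after the result was seen, and the gene lists were fixed earlier. Interferon response genes were often lower than in WAT in the UCP1-positive groups, where 20 to 22 of 22 macrophage markers were lower too, and whether they follow the macrophage content was not tested. They fell in 19 of 23 genes in BAT (19 adjusted over the list alone, adjusted p = 4.92e-10, and adjusted p = 0.189 with an estimated correlation). In CL 17 fell (18 adjusted over the list alone, adjusted p = 2.25e-11, and adjusted p = 0.214 with an estimated correlation). In RS 11 fell (15 adjusted over the list alone, adjusted p = 7.98e-08, and adjusted p = 0.387 with an estimated correlation). In RG 9 fell (13 lower and 2 higher adjusted over the list alone, adjusted p = 8.17e-07, and adjusted p = 0.33 with an estimated correlation). Oasl2, an antiviral protein, was lower by 2.85 log2 units in BAT, 2.20 in CL, 2.39 in RS and 1.96 in RG. Extracellular matrix genes fell in 24 of 28 in BAT (24 adjusted over the list alone, adjusted p = 6.03e-14, and adjusted p = 0.176 with an estimated correlation), among them Col14a1, a fibril-associated collagen, by 2.84 log2 units. Stromal and preadipocyte markers fell beside them in 16 of 20 genes (16 adjusted over the list alone, adjusted p = 9.18e-10, and adjusted p = 0.176 with an estimated correlation), and WAT 4 had the highest level of both lists, 1.85 and 1.91. Genes of the unfolded protein response fell in 9 of 20 in CL (14 lower and 1 higher adjusted over the list alone, adjusted p = 1.02e-06, and adjusted p = 0.162 with an estimated correlation), among them Sdf2l1, a chaperone cofactor, and Xbp1, a transcription factor, by 1.76 and 0.80 log2 units.

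Some positional Hox genes differed between the treated inguinal groups and BAT, where depot and treatment both differ. Hoxc8 was higher than in BAT by 1.90 log2 units in CL, 1.72 in RS and 2.57 in RG, and Hoxc10 by 1.13, 0.87 and 1.04. Hoxa5 was lower by 1.25, 1.24 and 1.78. Of 23 Hox genes, 3 were higher and 1 lower in CL against BAT (4 and 1 adjusted over the list alone, adjusted p = 0.039, and adjusted p = 0.548 with an estimated correlation). The blocked fit of limma called 0 of the 23 in CL and in RS against BAT, and 2 higher and 1 lower in RG against BAT. Genes sensitive to the phosphorylation of PPARG at a serine of its ligand-binding domain fell in 3 of 16 in RS against WAT and none rose (the same counts adjusted over the list alone, adjusted p = 0.786, and adjusted p = 0.874 with an estimated correlation), with a median of 0.22 and a mean of 0.03 above 0 where the test pointed down.

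Xist was 7.83 in RS 3, the highest of all arrays, against 5.68 or less elsewhere. All 3 Y-linked genes tested were lowest in RS 3, with Eif2s3y at 2.55, Kdm5d at 2.51 and Uty at 3.13. A larger share of RNA from female mice in RS 3 could give these values, and the labels give no sex. In WAT 1 and WAT 3 Xist was 5.68 and 5.26, with Uty at 4.19 and 4.72. Which other differences between the RS arrays go with sex was not tested.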
